A study of Mus musculus with 6 samples.

How the data were processed

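The 6 libraries were made from total RNA of mouse PTECs by fragmentation, random-primed first strand synthesis and dUTP-based second strand synthesis, per the labels' protocols. The authors deposited 1 table of FPKM values (fragments scaled to gene length and to the library's mapped fragments), 1 row per Ensembl mouse gene and 1 column per library, with the unit per the file headers. cutadapt, HISAT2 2.0.5 and StringTie are named in the submitters' processing notes, with no role given. The same notes name the human build hg19, although the samples and gene identifiers are mouse, and the build used for the values is not given in the sources used here. No coordinates come from the table. Every one of its 12105 genes has a mean FPKM of at least 0.5 in 1 or both infections (the smallest higher group mean is 0.5000), so a gene below that in both infections was not analysed here, and 99.7% of the genes are protein coding. Because FPKM is a share of each library, a rise in some genes lowers others. The values come without the read counts from which their counting error could be modelled.

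Identifiers were joined to gene symbols without their version: 12089 of 12105 matched and 16 did not. Coordinates, gene span (first to last annotated base), exon length (union of exons) and GC content of the longest transcript were taken from GENCODE M21 on GRCm38. Groups follow the infection named for each sample, and replicate numbers follow the titles. No pair of columns was identical, and replicates were treated as separate samples.

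The table holds no read counts. For genes with 1 annotated transcript, FPKM times exon length was tested for whole multiples of a common step. Among the lowest 150 values per library, 44% to 51.3% in Ad-FXRα2 and 23.3% to 37.3% in Ad-VP16 libraries lay within 0.05 of a whole multiple, against at most 20.7% after random jitter. The step was sought only inside a fixed range, which bounded the depths it could give. A smaller step, and so a higher depth, was not excluded. The step gave an estimate of the number of fragments per library, but many values were not whole, so reads were not recovered and no count test was run.

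The main test was limma 3.58.1 in R 4.3.3 (eBayes with trend) on log2(FPKM + 0.5), for 11507 genes with a mean FPKM of at least 0.5 over the 6 libraries, leaving out 598. It was two-sided with Benjamini-Hochberg adjustment at 0.05 and no fold threshold. Log2 fold changes are Ad-FXRα2 minus Ad-VP16 on that scale and understate the change of low genes. Errors of levels are SD over 3 libraries, and SE is limma's moderated standard error. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and, beside it, with an estimated correlation and with fry, adjusted over 25 lists. The tests, lists, rule for named genes and most alternatives were fixed before the data were examined. The rule names Nr1h4, the 5 largest rises and 5 largest falls among called, non-overlapping genes with a mean FPKM of at least 1 that are not predicted genes, antisense genes or pseudogenes, up to 2 called members of each gene list and 1 of each marker list by size of change, and Gpx4, Slc7a11, Acsl4, Havcr1 and Cdkn1a. A list with no called member gives its most abundant one. Some genes that the rule names are not reported here.

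The fit was tested on simulated data of 11507 genes with the residual spread of the real ones and 200 genes changed. It recovered 23.9% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 93.9% of those changed 4-fold, with 4 false calls (3.17% of calls). With so few genes changed the adjusted threshold was stricter than in the real data, so these shares are not the recovery there. A shifted list was called and 0 of 19 unshifted lists were. The simulated genes were drawn independently of each other, so this does not test the preset correlation on real lists. Their estimated correlation reached 0.439, for mitochondrial DNA genes.

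Alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 1, median-ratio scaling, quantile normalization, limma without trend or with robust fitting, a replicate block, each library left out, and a 1.5-fold threshold. A mean of at least 10 and removal of a fitted trend with gene span, exon length and GC content were added after seeing the data. Correlations across genes and their permutation tests used Python 3.11.15 with scipy 1.17.1.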

Results

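RNA sequencing was done on mouse primary proximal tubular epithelial cells (PTECs), cultured cells of the kidney segment that reabsorbs most of the filtrate. All 6 libraries came from wild-type PTECs given cisplatin, a platinum drug that crosslinks DNA and is toxic to this segment. 3 libraries were from cells infected with the adenovirus Ad-FXRα2 and 3 from cells infected with Ad-VP16. FXRα2 is an isoform of the farnesoid X receptor (FXR), a nuclear receptor for bile acids encoded by Nr1h4, and VP16 is the name of a viral transcription activator. The labels do not say whether Ad-FXRα2 carries a VP16 fusion, so it is open whether the infections differ in FXRα2 alone or also in an activator. The single comparison of the design asks how gene expression in cisplatin-treated PTECs differed between the Ad-FXRα2 and Ad-VP16 infections. No library of cells without cisplatin was analysed here, so the effect of cisplatin itself was not measured. The values were FPKM for 12105 genes, and they summed to between 294909 and 315217 per library. The depth is not stated. Part of the low values fell on steps, least clearly in Ad-VP16 replicate 1, and as an estimate these corresponded to about 5240000, 6740000 and 4930000 fragments in Ad-FXRα2 replicates 1, 2 and 3 and to about 8220000, 6440000 and 7080000 in Ad-VP16 replicates 1, 2 and 3. The search for steps covered a fixed range, which bounded these estimates, and a higher depth was not excluded. At these estimated depths a gene of 2 kb at an FPKM of 0.5 rests on 4.935 to 8.22 fragments. Pearson correlations of log2(FPKM + 0.5) across genes were 0.980 to 0.990 between libraries of the same infection and 0.815 to 0.827 between infections.

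Nr1h4 (ENSMUSG00000047638.15, chromosome 10, 89454234 to 89533585, GRCm38), the gene named by the vector, was at 16.1 ± 0.623 FPKM (SD, n = 3) in Ad-FXRα2 libraries. In Ad-VP16 libraries it was listed at 0 in replicates 2 and 3 and at 0.0533 FPKM in replicate 1. The exact permutation test (two-sided) gave p = 0.1, the smallest that 3 against 3 libraries allow, and the limma adjusted p was 2.15e-08. Reads from the vector and from the chromosomal gene were not separated.

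Most genes differed between the infections. Of 11507 genes tested with limma at a Benjamini-Hochberg adjusted p under 0.05, 3693 were higher and 4408 were lower in Ad-FXRα2 libraries, and 3406 did not pass. At least 2-fold changes on the log2(FPKM + 0.5) scale were found in 1980 of the higher and 2463 of the lower genes. The largest rises by the fixed rule, beside Nr1h4, were in Crabp1, C1ql1, Pbk and Khdrbs3. Crabp1, a cytosolic retinoic acid binding protein, was at 21.99 ± 1.02 FPKM (SD, n = 3) in Ad-FXRα2 libraries and listed at 0 in every Ad-VP16 library. C1ql1, a secreted C1q-like protein, was at 23.6 against 0.206 FPKM. Pbk, a mitotic kinase, rose from 1.60 ± 0.356 to 61.2 ± 0.468 FPKM, and Khdrbs3, an RNA-binding splicing regulator, rose from 0.974 ± 0.660 to 39.6 ± 3.07 FPKM (SD, n = 3). The largest falls were in the neutrophil-attracting chemokines Cxcl1 (77.7 ± 7.50 to 1.41 ± 0.218 FPKM) and Cxcl2 (76.3 ± 11.6 to 2.07 ± 0.504 FPKM), the chemokine Ccl20 (61.6 ± 14.3 to 1.16 ± 0.492 FPKM), the interleukin-1 family cytokine Il1f6 (57.9 ± 2.95 to 0.985 ± 0.295 FPKM) and Ddit4l, a stress-induced gene (75.8 ± 5.88 to 1.77 ± 0.677 FPKM). limma adjusted p was at most 2.63e-07 for these 9 genes. The groups did not overlap in 73.9% of the tested genes, where chance gives 10%. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

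**Figure D1:**
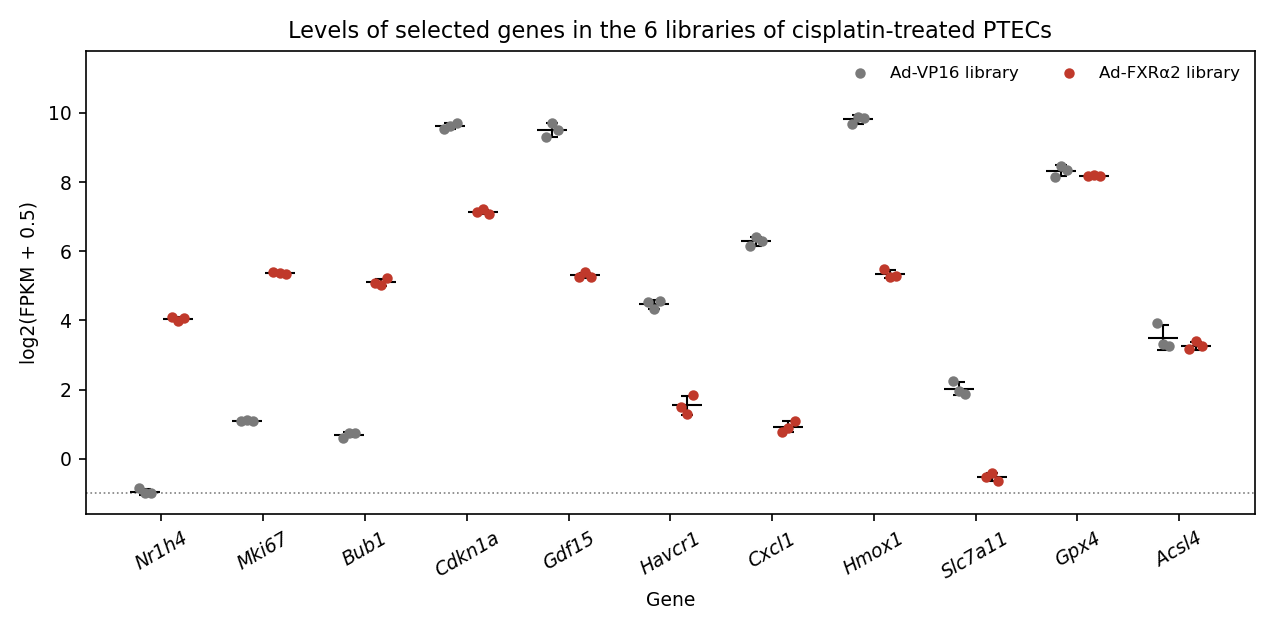
Levels of 11 genes on the log2(FPKM + 0.5) scale in each library, with the mean and SD over 3 libraries per infection in black and a dotted line at an FPKM of 0. Nr1h4, Mki67 and Bub1 were higher in the Ad-FXRα2 libraries, Cdkn1a, Gdf15, Havcr1, Cxcl1, Hmox1 and Slc7a11 were lower, and Gpx4 and Acsl4 overlapped between the infections.

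Members of 18 gene lists and 7 cell type marker lists were then counted. camera with its preset inter-gene correlation of 0.01 called 9 of the 25 lists, 8 lower and 1 higher, and with an estimated correlation it called 0, with 4 lists at an unadjusted p under 0.05. fry, which asks whether a list's genes move on balance in one direction and does not compare the list with other genes, called all 25. Adjusted over the list alone, the counts of members that rose or fell matched those over all genes tested, except for ferroptosis drivers (7 rose, not 6), ER stress genes (16 fell, not 15) and mitochondrial DNA genes (5 fell, not 7). The genes named outside the fixed rule were chosen after their values were seen.

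Proliferation genes were higher in Ad-FXRα2 libraries. Of 28 cell cycle genes 27 rose and 1 fell, with a median log2 fold change of 2.55. The mitotic checkpoint kinase Bub1 rose from 1.12 ± 0.0816 to 34.0 ± 2.46 FPKM (log2 fold change 4.41, SE 0.12). The proliferation marker Mki67 rose from 1.64 ± 0.0235 to 41.0 ± 1.01 FPKM (log2 fold change 4.28, SE 0.10). Genes that rose least were Rrm2 (0.20), Pcna (0.22) and Mcm7 (0.26), on the log2 scale. The exception was Ccnd1, the G1 cyclin D1, which fell from 99.8 ± 16.9 to 10.6 ± 0.291 FPKM. camera's adjusted p was 3.24e-11, and adjusted p = 0.050 with an estimated correlation (0.05025, above the threshold).

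Targets of the DNA damage regulator p53 were lower in Ad-FXRα2 libraries. Of 28 measured targets 26 fell and 1 rose, with a median log2 fold change of -2.13. Gdf15, a secreted stress cytokine, fell from 731.5 ± 104 to 39.2 ± 1.96 FPKM, and Trp53inp1, a p53 cofactor, fell from 203.7 ± 18.9 to 16.4 ± 0.951 FPKM. Cdkn1a, the cell cycle inhibitor p21, fell from 791.7 ± 46.8 to 140.4 ± 6.99 FPKM (log2 fold change -2.49, SE 0.07, limma adjusted p = 1.37e-08). Rrm2b, a ribonucleotide reductase subunit, rose from 2.65 to 4.48 FPKM. camera's adjusted p for the list was 4.56e-09, and adjusted p = 0.252 with an estimated correlation. Among 22 apoptosis regulators 14 fell and 3 rose. Cflar, an inhibitor of caspase 8, fell from 7.27 ± 0.807 to 1.14 ± 0.544 FPKM, and the anti-apoptotic genes Mcl1 and Bcl2l1 fell by 1.83 and 2.06 on the log2 scale. Those that rose included Birc5, which also acts in mitosis (1.78 ± 0.268 to 28.1 ± 1.40 FPKM), and Cycs, cytochrome c. The pro-apoptotic genes Bid and Bak1 fell by 1.71 and 0.90 on the log2 scale. camera's adjusted p was 0.0426, and adjusted p = 0.271 with an estimated correlation. The call also ended with a mean of at least 1 FPKM (0.0559), with a mean of at least 10 FPKM (0.348), with the trend with gene span, exon length and GC content removed (0.0654) and without Ad-FXRα2 replicate 2 (0.0576). The list median in these settings was, in order, -0.62, -0.51, -0.88 and -0.71, against -0.595 in the main test. Over the 17 alternatives that keep the preset correlation the adjusted p ranged from 0.0278 to 0.348.

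Markers of injured tubules were lower in Ad-FXRα2 libraries. Of 23 tubular injury and repair genes 22 fell and none rose, and Vim did not pass. Cd24a, a marker of injured and progenitor-like tubular cells, fell from 477.1 ± 10.4 to 58.7 ± 5.26 FPKM, and the keratin Krt20 fell from 62.3 ± 6.62 to 7.70 ± 1.72 FPKM. Havcr1, which encodes kidney injury molecule KIM-1, fell from 21.7 ± 1.98 to 2.46 ± 0.586 FPKM (log2 fold change -2.92, SE 0.16, limma adjusted p = 3.12e-07). The list median was -1.90, camera's adjusted p was 2.49e-07, and adjusted p = 0.110 with an estimated correlation.

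Inflammatory genes were also lower. Of 23 NF-κB inflammatory genes 20 fell and 3 rose, with a median log2 fold change of -2.98, the lowest of the lists with more than 1 measured member. Cxcl1 and Ccl20 led the list. The 3 that rose were Nfkbia, the inhibitor of NF-κB (62.2 ± 0.831 to 525.9 ± 55.7 FPKM), the NF-κB subunit Nfkb1 (1.31 to 2.68 FPKM) and the cytokine Il6, which was at 1.69, 3.27 and 2.87 FPKM in Ad-FXRα2 libraries and at 0.178 and 0.362 FPKM and listed at 0 in Ad-VP16 libraries. camera's adjusted p was 1.67e-05, and adjusted p = 0.140 with an estimated correlation. Of 23 interferon-stimulated genes 18 fell and none rose. Ifi35 fell from 16.4 ± 2.94 to 2.28 ± 0.903 FPKM and the viral RNA sensor relative Oasl1 from 19.1 ± 1.51 to 3.14 ± 0.504 FPKM. The list median was -0.89, camera's adjusted p was 0.00553, and adjusted p = 0.4815 with an estimated correlation. With a mean of at least 10 FPKM the call ended (0.185, the highest of the 17 alternatives that keep the preset correlation, with the lowest at 0.00178). Among macrophage and leukocyte markers 4 of 5 measured fell beside these lists. Cd14, the lipopolysaccharide co-receptor, fell from 36.0 ± 1.17 to 2.24 ± 0.848 FPKM.

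Ferroptosis is an iron-dependent cell death by lipid peroxidation. Of 25 genes listed as its suppressors 17 were lower and 4 higher in Ad-FXRα2 libraries, with a median log2 fold change of -1.21. Hmox1, heme oxygenase 1, fell from 901.8 ± 74.2 to 40.3 ± 3.47 FPKM, and the quinone reductase Nqo1 fell from 72.1 ± 2.84 to 9.87 ± 1.10 FPKM. Slc7a11, the cystine importer, fell from 3.60 ± 0.548 to 0.195 ± 0.0579 FPKM (log2 fold change -2.55, SE 0.20, limma adjusted p = 3.06e-06). Gpx4, the lipid hydroperoxide reductase, was at 291.8 ± 1.66 against 322.2 ± 35.2 FPKM and did not pass (log2 fold change -0.14, SE 0.08, limma adjusted p = 0.172). Without Ad-VP16 replicate 1 its limma adjusted p was 0.00756 at a log2 fold change of -0.22, where 17 alternatives ranged from 0.00756 to 0.781. The 4 that rose were Dhodh, Acsl3, Cisd1 and Pcbp1, at log2 fold changes of 1.33, 1.27, 1.11 and 0.42. Aifm2, the ubiquinone reductase FSP1, was at 4.53 against 3.73 FPKM and did not pass. camera's adjusted p for the list was 0.0032, and adjusted p = 0.257 with an estimated correlation. Of 19 genes listed as ferroptosis drivers 9 fell and 6 rose. The prostaglandin synthase Ptgs2 fell from 53.5 ± 5.42 to 6.71 ± 1.56 FPKM and the polyamine acetyltransferase Sat1 from 178.5 ± 10.2 to 24.3 ± 4.07 FPKM. Ptgs2 is in the list although it is read as a marker of ferroptosis rather than a driver. Acsl4, which loads membranes with polyunsaturated fatty acids, was at 9.19 ± 0.791 against 11.1 ± 3.07 FPKM and did not pass (log2 fold change -0.23, SE 0.17, limma adjusted p = 0.259). With the trend with gene span, exon length and GC content removed its log2 fold change was -0.94 and its limma adjusted p 0.00108, where 17 alternatives ranged up to 0.873. The driver list was not called by camera (adjusted p = 0.464).

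Glutathione and NRF2 response genes, of which several also stand in the ferroptosis suppressor list, were lower. Hmox1, Nqo1 and Slc7a11 are among the shared genes, so the falls of these lists are not separate results. Of 28 measured 24 fell, and the 2 that rose were Me1, a source of NADPH, and Sod2, the mitochondrial superoxide dismutase (15.4 to 24.98 FPKM). Gsta3, a glutathione transferase, fell from 34.5 ± 1.80 to 2.68 ± 0.700 FPKM, and whether it shares reads with its close paralogs was not tested. The list median was -1.67, camera's adjusted p was 8.44e-07, and adjusted p = 0.050 with an estimated correlation (0.05025, above the threshold).

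**Figure D2:**
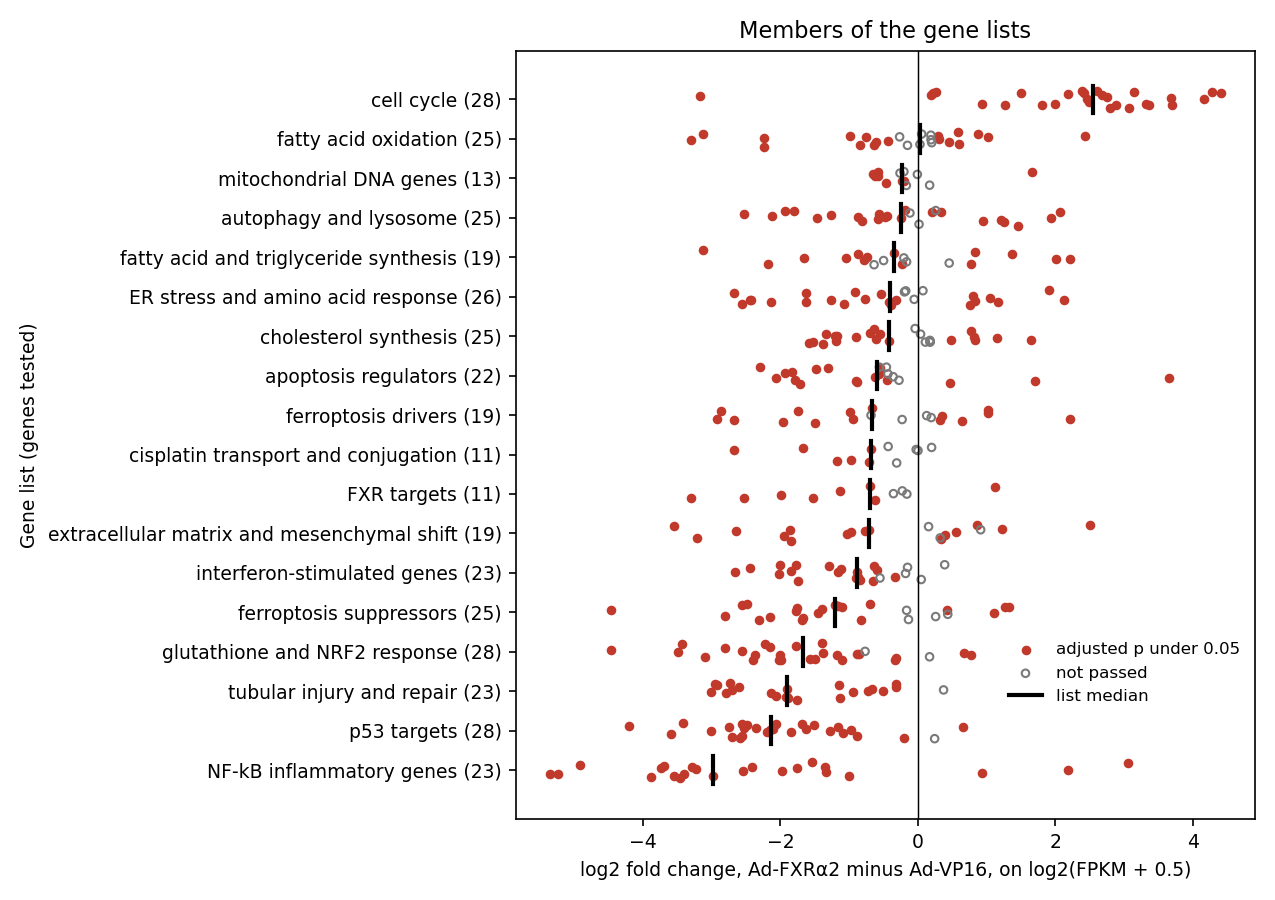
log2 fold changes of the tested members of 18 gene lists, Ad-FXRα2 minus Ad-VP16 on the log2(FPKM + 0.5) scale, filled where the limma adjusted p was under 0.05 and open otherwise, with the list median as a bar. Medians run from -2.98 for NF-κB inflammatory genes to 2.55 for cell cycle genes.

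Of 34 genes listed as FXR targets, mostly known from liver and intestine, 11 were tested and 23 were not analysed here. Of the 11, 7 fell and 1 rose in Ad-FXRα2 libraries. The list was not split into genes that FXR raises and genes that it lowers. Its direction therefore does not measure FXR activity. Pdk4, the kinase that inhibits pyruvate dehydrogenase, fell from 12.2 ± 2.72 to 0.787 ± 0.220 FPKM. The autophagy receptor Sqstm1 fell from 637.5 ± 163 to 107.9 ± 8.19 FPKM. Apoa1, the main protein of high-density lipoprotein, rose to 1.30, 1.01 and 0.663 FPKM, from 0.271 and 0.288 FPKM in Ad-VP16 replicates 2 and 3 and listed at 0 in replicate 1. The list median was -0.70, camera's adjusted p was 0.0426, and adjusted p = 0.401 with an estimated correlation. The call also ended without a filter on low values (0.08315), with a mean of at least 10 FPKM (0.104), with the trend with gene span, exon length and GC content removed (0.0504) and without Ad-FXRα2 replicate 2 (0.0768) or 3 (0.06786). Over the 17 alternatives that keep the preset correlation the adjusted p ranged from 0.00817 to 0.104.

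Lipid genes moved in both directions, and none of their lists was called. Of 25 fatty acid oxidation genes 10 fell and 8 rose. The list's median log2 fold change was 0.03, its mean was -0.34 and camera's direction was down (adjusted p = 0.85). Pdk4 and the lipid droplet coat protein Plin2 fell, Plin2 from 147.4 ± 8.38 to 16.4 ± 1.26 FPKM. Etfa, an electron carrier of this pathway, rose from 18.7 ± 3.81 to 101.5 ± 5.07 FPKM. Of 25 cholesterol synthesis and uptake genes 13 fell and 6 rose (adjusted p = 0.476). Msmo1, a sterol demethylase, fell from 16.6 ± 2.79 to 5.24 ± 1.09 FPKM. Of 19 fatty acid and triglyceride synthesis genes 9 fell and 5 rose (adjusted p = 0.411). Acaca, acetyl-CoA carboxylase, rose from 0.631 ± 0.306 to 4.63 ± 0.442 FPKM.

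The remaining gene lists were not called by camera. Of 26 ER stress and amino acid response genes 15 fell and 7 rose (adjusted p = 0.303). Chac1, a glutathione-degrading enzyme, fell from 4.79 ± 1.65 FPKM to 0.468 and 0.567 FPKM in Ad-FXRα2 replicates 1 and 2 and was listed at 0 in replicate 3. Sesn2, a stress-induced inhibitor of growth signalling, fell from 32.8 ± 5.61 to 5.26 ± 1.61 FPKM. Mthfd2, a mitochondrial folate enzyme, rose from 21.5 ± 1.01 to 81.7 ± 2.09 FPKM. Of 25 autophagy and lysosome genes 14 fell and 8 rose (adjusted p = 0.371), with falls in Sqstm1 and in Atg9b (40.1 ± 1.76 to 8.85 ± 0.547 FPKM). Of 11 measured genes of cisplatin transport and conjugation 6 fell and none rose (adjusted p = 0.0896). The lysosomal copper transporter Slc31a2 fell from 15.4 ± 4.76 to 1.94 ± 0.332 FPKM and the metallothionein Mt1 from 82.1 ± 11.3 to 25.3 ± 1.82 FPKM, while the main copper importer Slc31a1 was at 14.7 FPKM in both infections and did not pass. Of 19 extracellular matrix and mesenchymal genes 10 fell and 6 rose (adjusted p = 0.438). Ccn2, connective tissue growth factor, fell from 63.9 ± 32.4 to 6.24 ± 2.61 FPKM. Cdh1, E-cadherin, rose from 38.3 ± 9.81 to 88.1 ± 5.62 FPKM. Of 13 genes of mitochondrial DNA 7 fell, among them mt-Nd1 (3443 ± 130 to 2185 ± 104 FPKM), and 1 rose (adjusted p = 0.145). That one, mt-Atp6, was at 325.7 FPKM in Ad-FXRα2 replicate 1, at 2200 and 1890 FPKM in replicates 2 and 3, and at 331.2, 353.4 and 364.5 FPKM in the Ad-VP16 libraries, so that the groups overlapped. Its gene overlaps mt-Atp8, and its call (limma adjusted p = 0.0291) ended without Ad-FXRα2 replicate 2 (0.107) or 3 (0.113), or without Ad-VP16 replicate 1, 2 or 3 (0.0848, 0.0638 and 0.0552), and in limma without trend (0.0665) or with robust fitting (0.148). Over 17 alternatives it ranged from 6.36e-07 to 0.148. The list itself passed under quantile normalization (adjusted p = 0.0130) and without Ad-VP16 replicate 1 (0.0495), with up to 0.438 in other alternatives that keep the preset correlation, and adjusted p = 0.5875 with an estimated correlation.

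More cell type markers were lower than higher in Ad-FXRα2 libraries. Of 31 proximal tubule markers 5 were tested and 26 were not analysed here. Those 26 had no matched value or a mean FPKM under 0.5 over the 6 libraries. How far the cells kept a proximal tubule identity was therefore not tested. The water channel Aqp1 fell from 5.22 ± 1.80 to 1.16 ± 0.770 FPKM, Slc3a1 also fell, and the creatine synthesis enzyme Gatm rose from 2.48 to 5.77 FPKM. In the distal tubule list 3 of 5 fell, with Wnk4 going from 4.29 ± 0.290 FPKM to 1.15 and 1.06 FPKM in Ad-FXRα2 replicates 2 and 3 and listed at 0 in replicate 1, and Ppp1r1a rose. In the collecting duct list 4 of 7 fell, with Hsd11b2 going from 5.91 ± 1.55 to 1.27 ± 0.251 FPKM. In the podocyte and parietal cell list 5 of 6 fell, led by the tight junction gene Cldn1 (25.2 ± 6.53 to 1.56 ± 0.114 FPKM). This list passed under median-ratio scaling (adjusted p = 0.0404), quantile normalization (0.0377) and without Ad-VP16 replicate 1 (0.0285) or 3 (0.0465), with up to 0.201 in other alternatives that keep the preset correlation, and adjusted p = 0.271 with an estimated correlation. The only fibroblast and pericyte marker tested, S100a4, fell from 16.9 ± 0.691 to 4.22 ± 1.14 FPKM. Among 4 endothelial markers Plvap rose from 0.392 ± 0.164 to 21.03 ± 3.83 FPKM and Egfl7 from 1.17 to 5.35 FPKM, while Eng (1.40 to 1.22 FPKM) and Esam (1.12 to 0.611 FPKM) did not pass. None of the 7 marker lists was called by camera, with adjusted p between 0.0586 and 0.610.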

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

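The mean of at least 10 FPKM and the removal of the trend with gene span, exon length and GC content were chosen after seeing the data. limma called 8101 genes. With other pseudocounts, filters up to a mean of at least 1 FPKM, scalings and fitting options the count ranged from 7458 to 8502, and 0 of the 8101 calls changed sign. A 1.5-fold threshold left 6824 genes, 3068 higher and 3756 lower. With the trend with gene span, exon length and GC content removed 7844 genes were called, 6778 of the 8101 were called again and 227 changed sign. With a mean of at least 10 FPKM 3149 genes were called, 1491 higher and 1658 lower, because only 3865 were tested, and 5 lists were called lower, with the single higher list kept. Leaving out each library in turn gave 7474 to 8095 genes, 3377 to 3983 higher and 4080 to 4236 lower. Without Ad-VP16 replicate 1 the split was 3983 higher against 4112 lower, and quantile normalization gave 4178 against 4145. The median log2 fold change of all genes was -0.10 as reported, -0.02 under median-ratio scaling and -0.01 under quantile normalization. The 9 called lists (8 lower, 1 higher) became 0 with an estimated correlation in camera, 0 higher and 0 lower, where 4 lists had an unadjusted p under 0.05, and 25 with fry, 2 higher and 23 lower, which asks another question. Same-numbered replicates of the infections had residual correlations of 0.00867, 0.0533 and -0.0179. Ad-FXRα2 replicates 1 and 2 correlated best with their own number, and replicate 3 with Ad-VP16 replicate 1. These low values gave no ground for pairing the libraries by number, but they cannot show that no animal or day is shared. With a replicate block 8065 genes were called, and the Nr1h4 log2 fold change was 5.01. Among the 51 genes named by the rule besides Nr1h4 and the 25 lists, 7 and 19 calls were lost and 2 and 22 were gained over all settings, with the estimated correlation and fry included, and 0 reversed. At the estimated depths genes near an FPKM of 0.5 rest on few fragments, and each infection has 3 libraries. A gene that did not pass is therefore not shown to be equal between the infections. In the simulated data 23.9% of 1.5-fold changes were recovered, but only 200 of 11507 genes were changed there. That makes the adjusted threshold stricter than with 8101 calls, so the share is not the recovery in this comparison.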

Other observations

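The tests on protein families, on exon length, GC content and level, on genes of non-epithelial cells, on scaling and on other splits of the libraries were chosen only after the result was seen. In several protein families, grouped by symbol after the largest changes had been seen, more genes moved one way than the other. Cytosolic ribosomal protein genes and their paralogs rose in 58 of 81 cases and fell in 7 (median log2 fold change 0.41, and 0.50 and 0.39 under median-ratio and quantile scaling), and Rps2 went from 966.5 to 2337 FPKM. Mitochondrial ribosomal protein genes rose in 46 of 78 cases and complex I subunits in 23 of 35. Centromere proteins rose in 19 of 21 cases, among them Cenph (1.71 to 35.8 FPKM). Claudins, which form tight junctions, fell in 9 of 10 cases, among them Cldn4 (553.1 to 35.4 FPKM), and keratins fell in 12 of 14. Small proline-rich and late cornified envelope genes, which are best known from skin barrier, fell in 11 of 11 cases, and S100 genes in 9 of 12. Of 300 zinc finger protein genes 143 fell and 30 rose. camera with its preset correlation called 14 of the 15 families. With an estimated correlation it called 0, with 4 at an unadjusted p under 0.05 and the lowest adjusted p at 0.0609 for centromere proteins.

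Longer genes rose and shorter genes fell more often than the reverse. In the 1150 genes with the shortest span (up to 3.99 kb) the median log2 fold change was -0.35, with 25.9% risen and 46.4% fallen. In the 1150 with the longest (99.7 kb to 2961 kb) it was 0.74, with 53.4% risen and 11.04% fallen. Across 11493 genes, which are not independent replicates, Spearman's rho of the fold change with gene span was 0.26, and 0.271 with exon length, GC content and mean level held fixed, which argues against those as the cause (permutation p = 0.0001 for both, the smallest that 10000 permutations give). A lower depth of the Ad-FXRα2 libraries, which is uncertain because the estimated depths overlap between the infections, is argued against as the cause by a rho of 0.201 among genes with a mean of at least 10 FPKM. A candidate explanation is less transcription through long genes in the Ad-VP16 libraries, as DNA lesions that block polymerases would give. Inside these longest 1150 genes the trend continued, with a partial rho of 0.173 (permutation p = 1e-05, the smallest that 100000 permutations give). Other causes tied to gene span would give this too, so it does not single out this explanation, and without untreated cells or intronic reads it stays a hypothesis.

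Cell cycle genes rose while p53 target, injury and NF-κB genes fell. The trend with gene span, exon length and GC content does not account for this: with the trend removed the list medians were 2.77, -1.93, -1.73 and -2.63, so that the smallest was 1.73 from 0. The cell cycle genes have a median span of only 13.7 kb, so their rise runs against the trend. The p53 target, injury and NF-κB genes have median spans of 16.15, 7.86 and 6.87 kb. Their falls run with the trend and were somewhat smaller once it was removed. Non-epithelial cells in place of tubular epithelium would raise abundant genes of such cells. Of 21 such genes 9 were tested: 7 fell, 0 rose and the median log2 fold change was -0.737. The set did not rise, but it cannot decide the question. S100a6 (429.4 to 256.1 FPKM) and Lgals1 (421.1 to 299.8 FPKM) were at levels like the epithelial gene Epcam (259.3 to 309.7 FPKM). The epithelial cells themselves may therefore express them. Vim (2.00 to 2.74 FPKM) and Lyz2 (1.65 to 2.26 FPKM) were low and did not pass. Outside this set the endothelial markers Plvap and Egfl7 rose, while Eng and Esam did not pass. Non-epithelial cells in place of epithelium would also lower general epithelial genes by more than 1 log2 unit as a set, a prediction written afterwards. These genes had a median of -0.50, with 11 of 20 fallen and 5 risen. Krt7, Krt8, Krt18 and Krt19, which fell, are also in the injury list, so this set is not separate from the pattern. A change in the kind of epithelial cell stays open. Less DNA damage signalling, a different survival of damaged cells and a difference in culture or timing between the infections, for which the labels give no run, date or culture, stay open and were not tested.

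Most genes differed between the infections. A library-wide scaling difference is argued against as the cause, since 96.3% of the 8101 calls held under median-ratio scaling and 96% under quantile normalization. These scalings moved the median log2 fold change of all genes only from -0.10 to -0.02 and -0.01. They cannot show whether the infections differed in total RNA. Among the 10 splits of the 6 libraries 1, the real one, gave as many genes, and the highest count of another split in limma was 0 (19 to 97 genes at an unadjusted p under 0.05). For lists, 1 split of 10 gave the 9 called lists and the highest other gave 8. Each other split mixes the infections, which leaves part of their difference in the contrast and part in the spread, so these counts do not show how many genes or lists chance would call. With 10 splits a share under 0.05 cannot be reached in either case.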
